A study of Mus musculus with 6 samples.

How the data were processed

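RNA was measured in cultured colon fibroblasts of C57BL/6 mice aged 12 weeks, in 3 libraries labelled WT and 3 labelled Prkcz-/-. Per the labels' protocols, the cells received no treatment and were collected 24 h after plating at about 80% confluency. Polyadenylated RNA was made into strand-specific libraries with a directional kit and read from a single end on a NextSeq 500 instrument. Per the submitters' processing notes, the build was mm10 and the tools included STAR and DESeq2, whose roles and versions were not given in the sources used here. The program that assigned reads to genes, the gene annotation and the strand setting were also not given in the sources used here.

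The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to depth) for 16874 genes, with 1 column for each library. No gene was listed at 0 in all 6 libraries, and no gene encoded by the mitochondrial genome had a row. Low values mostly stepped in whole reads, with a step that depended on the gene and the library. Among genes under 0.15 FPKM in each library and above 0.0001 FPKM in both libraries compared, 85.2% to 87.2% of ratios to WT library 1 were ratios of small whole numbers (up to 20 over up to 6, tolerance 0.01). From these steps and annotated exon lengths, depth was estimated at 13100000 to 14800000 reads per library. It is an approximation, since the gene lengths used by the authors are not given in the sources used here. The libraries of both groups overlapped in this estimate (WT 13100000 to 14400000, labelled Prkcz-/- 13100000 to 14800000 reads). The table also held 298 values above 0 but under 0.0001 FPKM, in 84 genes, and values of 0 are therefore described only as listed at 0.

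The FPKM values are not counts, so no count model was fitted. Genes with a mean of at least 0.5 FPKM over the 6 libraries were kept (12130 of 16874), and log2(FPKM + 0.5) was compared between the groups with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend). The tests were two-sided, and an adjusted p under 0.05 after Benjamini-Hochberg adjustment was the threshold. Fold changes given as log2 are on this log2(FPKM + 0.5) scale, which understates the change of genes with low values. Prkcz, Sox2, Sfrp1 and Sfrp2 also had an exact permutation test. On values simulated for the 12130 genes of this comparison, the limma fit recovered 48 of 50 genes changed 1.5-fold and 50 of 50 at each of 2-fold, 4-fold and 8-fold, with 5 calls among 11930 unchanged genes. The simulation changed a far smaller share of genes than was called in the data. Its changed genes lay above a low-value floor in WT, and its noise was independent with the fitted spread. It checks that the fit works in that setting and does not test the calls made here.

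Before the data were examined, 44 gene lists with 940 entries were fixed, covering fibroblast pathways, markers of other cell types and signs of RNA quality. The 33 lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, adjusted over these lists. Camera with an estimated correlation was run beside it, as was fry, which asks another question: camera compares a list with the other genes, while fry tests it against no change. Named genes were also chosen by a rule fixed before the data were examined. It took Prkcz, Sox2, Sfrp1 and Sfrp2, then the 12 genes with the highest and the 12 with the lowest log2 fold change. Those genes had to pass the threshold, have groups that did not overlap, reach a mean of 2 FPKM in the higher group and carry a symbol that is not a predicted gene model. From each pathway list the rule took up to 4 members with the smallest p-value, and from each list of other cell types or quality the 2 members with the highest mean FPKM. Genes named outside the rule are marked as chosen after their values were seen, with some exceptions. Rps4x, Hoxc5, Ctla2b, Stx5a, Ncl, Sox2ot and Gm27200 are named only as near copies or overlapping genes. Mir6236 is named for its share of the FPKM sum. Some genes that the rule selects are not reported here.

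Positions are from GENCODE M21 on GRCm38 (mm10). By symbol, 16175 of the 16874 genes matched 1 annotated gene. The alternatives fixed beforehand were other pseudocounts, filters, scalings, thresholds, variance models and library weights, a block for the replicate number, and leaving out each library. The alternatives planned for a table of counts were not run, because the table holds no counts. Removing chromosome medians, leaving out both number 1 libraries, and rescaling without short RNA genes were added after seeing the data.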

Results

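Gene expression was measured by RNA sequencing in colon fibroblasts, the connective tissue cells of the large bowel, taken from mice labelled WT and from mice labelled Prkcz-/-. Prkcz encodes the atypical protein kinase C zeta. Each group had 3 libraries, at an estimated 13100000 to 14800000 reads each. The series' design text also speaks of control guide and Sox2 guide cells and of more replicates. The labels of these 6 libraries give only the genotype, so whether the cells carried a guide is not known here. Nothing in the labels says that the libraries of a group came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical. The library titles of each group share the same prefix and differ only in a serial number. That may mean a single line per group, but the labels do not say so. Across genes, Pearson's r of log2 values lay between 0.982 and 0.984 within groups and between 0.907 and 0.911 across groups; genes are not independent replicates. Between 1614 and 1733 genes were listed at 0 in the libraries labelled Prkcz-/-, and between 2218 and 2296 in those labelled WT.

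Prkcz, the targeted gene, went against the labels. It lies on the minus strand of chromosome 4 (155260129 to 155361361) and measured 0.0433, 0.144 and 0.202 FPKM in WT libraries 1 to 3 but 1.35, 1.32 and 1.17 FPKM in the libraries labelled Prkcz-/-. The difference in log2 was 1.51 (SE 0.148, limma adjusted p = 4.65e-05), at roughly 4.0 to 18.4 against 107 to 124 reads. A value for the whole gene does not show whether a deleted part was read. The antisense gene Gm27200 overlaps Prkcz on the plus strand, so reads could be shared if strand was ignored. Directions are therefore given throughout for the libraries labelled Prkcz-/- relative to those labelled WT, and "higher" and "lower" mean no more than that.

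The comparison of the 2 labelled groups addresses which genes differ between fibroblasts labelled Prkcz-/- and WT, and the series title names Sox2, Sfrp1 and Sfrp2. All 3 were higher in the libraries labelled Prkcz-/-. Sox2, a transcription factor of stem and progenitor cells (chromosome 3, 34650405 to 34652461), rose from 0.470 ± 0.384 to 20.9 ± 0.611 FPKM (SD, n = 3), a log2 change of 4.54 (SE 0.262, limma adjusted p = 2.46e-06). It lies within Sox2ot on the same strand, so reads could be shared. Sfrp1, a secreted WNT antagonist (chromosome 8, 23411502 to 23449632), rose from 0.219 ± 0.0813 to 138 ± 2.60 FPKM (SD, n = 3), a log2 change of 7.59 (SE 0.0828, limma adjusted p = 1.29e-09). Sfrp2, its relative (chromosome 3, 83766321 to 83774316), rose less, from 11.2 ± 1.78 to 19.3 ± 1.41 FPKM (SD, n = 3), a log2 change of 0.76 (SE 0.105, limma adjusted p = 3.21e-04). These genes were named by the study, possibly from these libraries, and their direction is not independent evidence. The exact permutation test gave p = 0.1 for each of the 4 genes, the smallest that 3 against 3 can give.

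**Figure D1:**
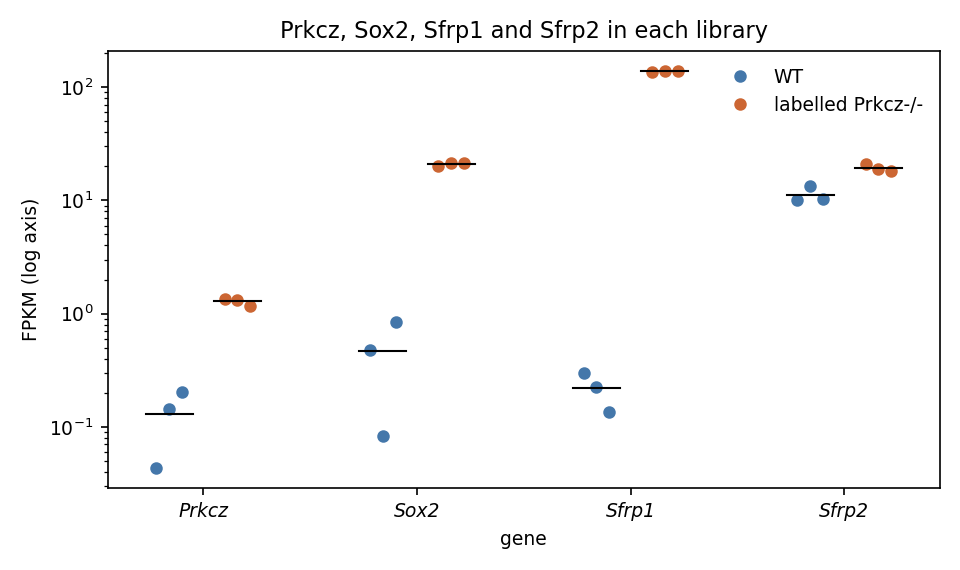
FPKM of Prkcz, Sox2, Sfrp1 and Sfrp2 on a log axis, with 1 point per library and a black line at each group mean. For each gene the 3 libraries labelled Prkcz-/- lie above the 3 labelled WT, with Sfrp1 at 135 to 140 against 0.135 to 0.298 FPKM.

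Of 12130 genes tested, 3825 were higher and 4511 lower in the libraries labelled Prkcz-/- (limma, adjusted p under 0.05), which is 68.7% of those tested. The balance turned with the scaling, to 4168 higher and 4064 lower with median-ratio scaling, and to 4464 and 3710 without short RNA genes. With a log2 change of at least 1 as well, 884 were higher and 431 lower. The median log2 change of all tested genes was -0.04, and the groups did not overlap for 72.7% of genes, where chance gives 10% for 3 against 3. That chance value assumes independent libraries, which the labels do not show, so the contrast does not tell genotype from culture.

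The 12 genes that rose most had limma adjusted p of 1.29e-06 or less. Besides Sfrp1, Wisp2, a secreted CCN family protein, rose from 1.46 ± 0.116 to 263 ± 4.12 FPKM (SD, n = 3), and Rarres1 from 0.0639 ± 0.0256 to 20.5 ± 0.327 FPKM. Prrx1, a homeobox factor of limb and fibroblast mesenchyme, rose from 3.42 ± 0.132 to 165 ± 3.36 FPKM. Hand2 rose from 0.387 ± 0.118 to 38.9 ± 2.45 FPKM and Shox2 from 0.666 ± 0.260 to 44.1 ± 1.22 FPKM. Hoxc6 measured 22.8 ± 0.417 FPKM in the libraries labelled Prkcz-/- and was above 0 in 1 WT library, at 0.0898 FPKM. Hoxc9 was listed at 0 in each WT library and measured 18.98, 20.8 and 18.2 FPKM in the others. Both overlap Hoxc5 on the same strand, so reads may be split among them. The imprinted gene Nnat reached 52.95 ± 2.09 FPKM, Sorbs2 24.3 ± 1.10 FPKM and Rgcc 30.8 ± 2.74 FPKM, from WT means of 0.0539, 0.0361 and 0.363 FPKM. Rps4l rose from 0.0254 to 38.4 ± 3.59 FPKM, a value that is uncertain because reads could be shared with its near copy Rps4x (713 FPKM in WT and 496 FPKM in the libraries labelled Prkcz-/-), which is named only as that copy.

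The 12 genes that fell most had limma adjusted p of 1.44e-06 or less. Adcyap1r1, the receptor of the neuropeptide PACAP, fell from 57.6 ± 5.32 to 0.367 ± 0.00865 FPKM (SD, n = 3), and Dpt, which encodes the matrix protein dermatopontin, from 88.4 ± 1.15 to 1.52 ± 0.239 FPKM. Ptgis, the prostacyclin synthase, fell from 82.3 ± 6.84 to 2.43 ± 0.188 FPKM. Rspo3, a secreted enhancer of WNT signalling, fell from 25.6 ± 1.38 to 0.837 ± 0.140 FPKM. The hindlimb and hindgut factors Pitx1 and Hoxd13 fell from 39.7 ± 2.63 to 1.07 ± 0.199 FPKM and from 40.6 ± 2.12 to 1.28 ± 0.322 FPKM. Asb5, Brinp1 and Mab21l2 fell from WT means of 57.2, 17.0 and 22.5 FPKM to 1.58, 0.125 and 0.852 FPKM. Ctla2a fell from 23.5 to 0.798 FPKM, with reads possibly shared with Ctla2b. Mir6992 and Snora75 were listed at 0 in each library labelled Prkcz-/- and measured 17.0 to 18.8 and 13.5 to 14.9 FPKM in WT. Both are short RNAs inside Stx5a and Ncl, for which FPKM in a polyadenylated library is uncertain. In WT libraries 1 to 3 Mir6992 measured 17.02, 18.83 and 17.24 FPKM and Snora75 13.49, 14.93 and 13.64 FPKM. These values closely follow the worth of 1 read relative to WT library 1 (1.1067 in WT library 2, 1.0 in WT library 3). They may thus stand for the same number of reads, possibly very few, in each WT library. The spread among the WT values of Mir6992 and Snora75, on which their adjusted p partly rests, may then reflect depth alone. That concerns the spread and not the difference between the groups, whose estimated depths overlapped.

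Genes of cholesterol synthesis fell together. Of 24 tested members 0 rose and 22 fell, with a median log2 change of -1.08 (camera adjusted p = 1.48e-08; adjusted p = 0.0755 with an estimated correlation). Msmo1 and Sc5d, enzymes of the late pathway, fell from 98.5 to 31.2 and from 53.03 to 24.1 FPKM. In the list of glycolysis and hypoxia genes, 16 of 24 fell and 4 rose (median log2 change -0.91, camera adjusted p = 0.00216; adjusted p = 0.187 with an estimated correlation). The lactate exporter Slc16a3 fell from 47.8 to 3.70 FPKM and Ldha from 770 to 263 FPKM, Gpi1 fell from 136 to 53.1 FPKM, and Ndrg1 rose from 19.6 to 58.6 FPKM. Of 20 NRF2 antioxidant genes 14 fell and 5 rose (camera adjusted p = 0.0275; adjusted p = 0.212 with an estimated correlation and 0.0683 with quantile normalization), with Tkt at 136 and 54.8 FPKM and Gsta4, which rose, at 3.67 and 32.7 FPKM in WT and the libraries labelled Prkcz-/-.

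Proliferation genes were lower by smaller amounts. In the mitosis list 28 of 30 fell and 0 rose (median log2 change -0.49, camera adjusted p = 3.11e-07), and in the DNA replication list 27 of 30 fell and 2 rose (median -0.36, camera adjusted p = 4.95e-05). Both had an adjusted p = 0.0895 with an estimated correlation. Kif23 fell from 53.7 to 25.4 FPKM, Ccnb2 from 118 to 62.2 FPKM, Gins2 from 85.2 to 45.7 FPKM and Slbp from 72.8 to 43.2 FPKM. Of 51 cytosolic ribosomal protein genes, listed as a sign of RNA quality, 44 fell and 0 rose (median -0.31, camera adjusted p = 1.28e-06; adjusted p = 0.407 with an estimated correlation), and Rplp1 fell from 3785 to 2852 FPKM. Among p53 targets and senescence genes 11 of 20 rose and 4 fell (camera adjusted p = 0.0275; adjusted p = 0.187 with an estimated correlation), with Cdkn1c rising from 4.33 to 14.02 FPKM, Fas from 4.65 to 16.6 FPKM, and Lmnb1, which senescent cells lose, falling from 97.1 to 60.1 FPKM.

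**Figure D2:**
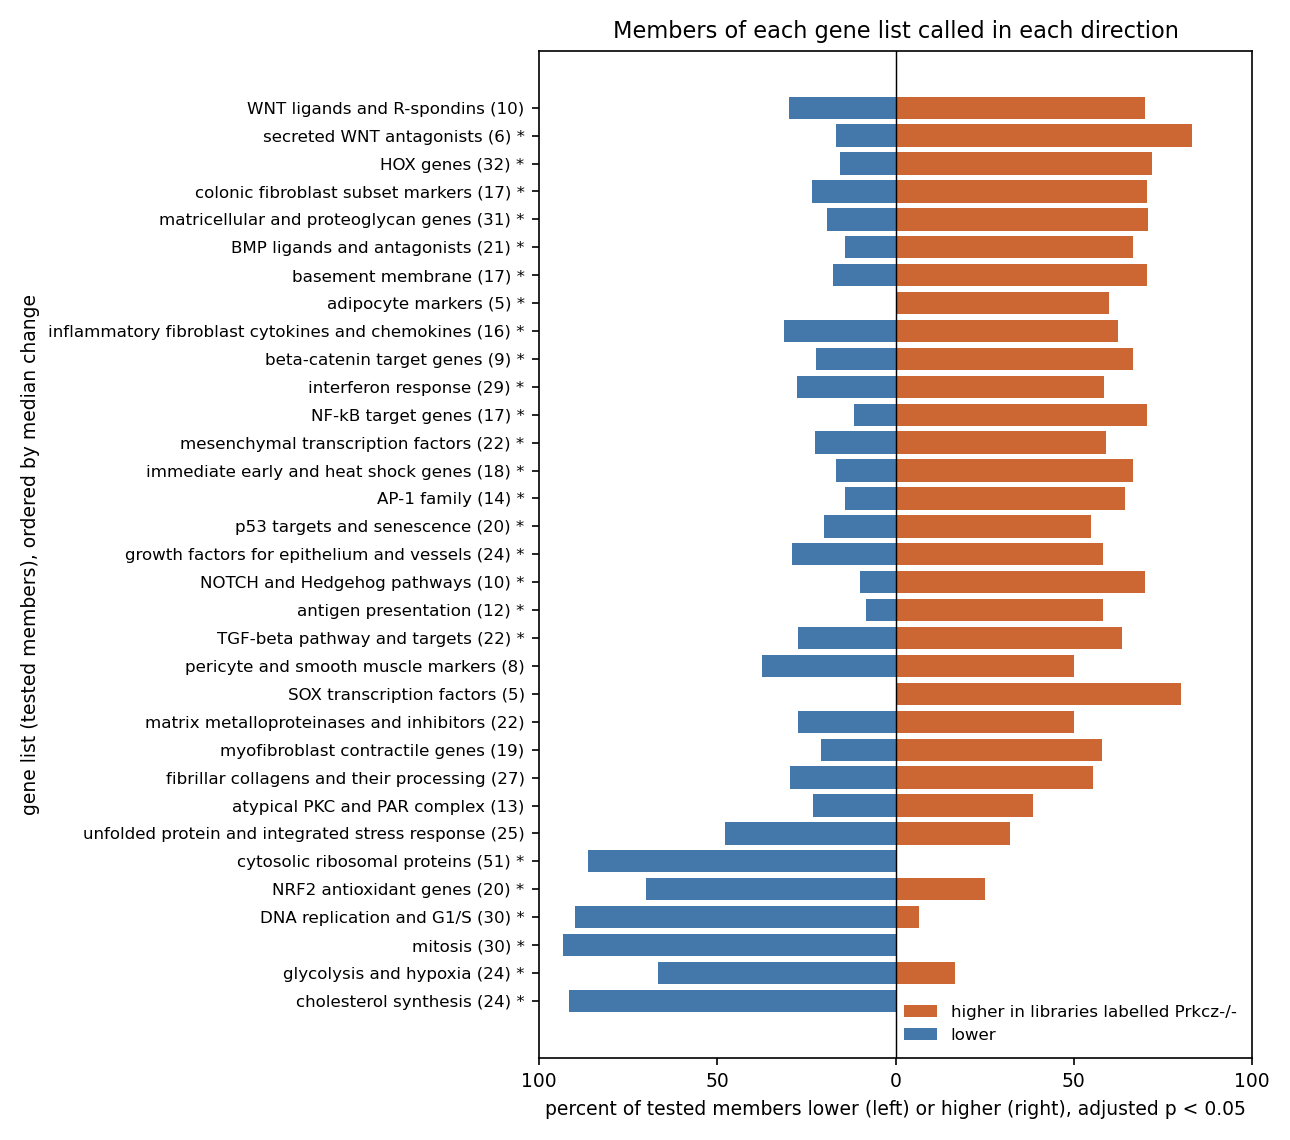
Share of the tested members of each gene list, in percent, that were higher (right) or lower (left) in the libraries labelled Prkcz-/- at a limma adjusted p under 0.05, ordered by median log2 change. The number of tested members is in parentheses, and an asterisk marks a camera adjusted p under 0.05 at the preset correlation, which 25 of 33 lists reached. Cholesterol synthesis, at the bottom, had 22 of 24 members lower.

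Secreted WNT antagonists rose: 5 of 6 tested members were higher and 1 lower (camera adjusted p = 0.0133; adjusted p = 0.187 with an estimated correlation), and the list holds Sfrp1 and Sfrp2, which the study chose. Dkk3 rose from 6.97 ± 0.546 to 182 ± 3.54 FPKM (SD, n = 3), Notum from 0.0447 to 1.02 FPKM and Dkk2 from 2.54 to 4.41 FPKM. WNT ligands and R-spondins went both ways, with 7 of 10 higher and 3 lower (camera adjusted p = 0.0594, but 0.047 without WT replicate 1 and 0.0338 with no filter on low values). Rspo2 rose from 3.37 to 55.8 FPKM and Wnt16 from 0.0399 to 11.7 FPKM, while Rspo3 fell. Of 9 beta-catenin target genes 6 rose and 2 fell (camera adjusted p = 0.04996; adjusted p = 0.199 with an estimated correlation), a call that most other settings ended, at 0.0519 to 0.107, among them leaving out any 1 library but WT replicate 1, with Myc rising from 19.2 to 43.3 FPKM and Ccnd1 falling from 38.2 to 20.9 FPKM. Among BMP ligands and antagonists 14 of 21 rose and 3 fell (camera adjusted p = 0.00331; adjusted p = 0.187 with an estimated correlation). The BMP antagonist Grem1 rose from 105 to 212 FPKM, the BMP target Id3 rose from 151 to 337 FPKM, and Bmper fell from 23.8 to 3.41 FPKM. In the TGF-beta list 14 of 22 rose and 6 fell (camera adjusted p = 0.0249; adjusted p = 0.227 with an estimated correlation), with Tgfbi rising from 6.91 to 167 FPKM, Tgfb3 from 8.95 to 78.9 FPKM and Tgfbr3 falling from 19.2 to 5.01 FPKM. NOTCH and Hedgehog genes had 7 of 10 higher and 1 lower (camera adjusted p = 0.00901; adjusted p = 0.199 with an estimated correlation), among them the ligand Jag1, from 2.43 to 16.3 FPKM.

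Matrix genes moved in both directions. Of 31 matricellular and proteoglycan genes 22 rose and 6 fell (camera adjusted p = 4.26e-04; adjusted p = 0.187 with an estimated correlation), with Fbln2 falling from 440 to 162 FPKM and Aspn rising from 13.2 to 38.6 FPKM. Of 17 basement membrane genes 12 rose and 3 fell (camera adjusted p = 0.00446; adjusted p = 0.32 with an estimated correlation). Lama4, Lama5 and Col15a1 rose from 1.15 to 48.1, 0.937 to 23.0 and 0.117 to 21.1 FPKM. Fibrillar collagens and their enzymes had 15 of 27 higher and 8 lower (camera adjusted p = 0.0594, but 0.0472 without WT replicate 2, 0.0378 with chromosome medians removed and 0.00957 with quantile normalization), with Col12a1 at 22.0 and 195 FPKM, Col6a2 at 34.4 and 251 FPKM, and P4ha1 at 148 and 59.2 FPKM in WT and the libraries labelled Prkcz-/-. Matrix metalloproteinases and inhibitors had 11 of 22 higher and 6 lower (camera adjusted p = 0.0907). Timp3 rose from 41.1 to 376 FPKM and Adamts5 fell from 59.6 to 16.02 FPKM. Of 19 myofibroblast contractile genes 11 rose and 4 fell (camera adjusted p = 0.121, but 0.0455 with chromosome medians removed and 0.0134 with quantile normalization), with a median log2 change of 0.17 and a mean of -0.02. Actg2 fell from 461 to 52.9 FPKM and Mylk from 12.8 to 3.29 FPKM, while Cnn2 rose from 313 to 581 FPKM.

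Among markers of colonic fibroblast subsets 12 of 17 rose and 4 fell (camera adjusted p = 0.0127; adjusted p = 0.187 with an estimated correlation). Cd34 fell from 517 ± 8.70 to 57.8 ± 1.65 FPKM (SD, n = 3), while Pdgfrb rose from 35.0 ± 0.930 to 99.6 ± 0.515 FPKM and F3 from 49.5 ± 1.84 to 122 ± 1.80 FPKM. In the list of epithelial and vascular growth factors 14 of 24 rose and 7 fell (camera adjusted p = 0.0133; adjusted p = 0.187 with an estimated correlation), with Fgf7 rising from 24.7 to 86.7 FPKM, Pdgfc from 4.40 to 22.1 FPKM and Hgf falling from 10.99 to 0.727 FPKM.

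Inflammatory lists had more members higher than lower, but besides camera with an estimated correlation, which ended every list call, other settings ended the call of 4 of them. Of 16 cytokine and chemokine genes 10 rose and 5 fell (camera adjusted p = 0.0397; adjusted p = 0.187 with an estimated correlation, 0.0629 with median-ratio scaling and 0.0767 without short RNA genes), with Ccl2 rising from 23.7 ± 0.994 to 191 ± 7.72 FPKM (SD, n = 3), Ccl7 from 10.3 ± 1.56 to 144 ± 4.37 FPKM and Ccl5 from 19.2 ± 1.04 to 66.5 ± 5.02 FPKM. Of 17 NF-kB targets 12 rose and 2 fell (camera adjusted p = 0.0066; adjusted p = 0.187 with an estimated correlation), including Nfkbia, from 17.3 to 54.9 FPKM. The AP-1 family had 9 of 14 higher and 2 lower (camera adjusted p = 0.0288; adjusted p = 0.187 with an estimated correlation, 0.0535 with chromosome medians removed and 0.0517 without WT replicate 2), and Jun rose from 19.6 to 53.3 FPKM. Immediate early and heat shock genes, a sign of handling, had 12 of 18 higher and 3 lower (camera adjusted p = 0.0284; adjusted p = 0.32 with an estimated correlation), although Egr1 and Hsph1, the most abundant, fell from 53.4 to 39.8 and from 62.2 to 46.2 FPKM. Of 29 interferon response genes 17 rose and 8 fell (camera adjusted p = 0.0372; adjusted p = 0.648 with an estimated correlation). The interferon call also ended with no filter on low values (0.0512), short RNA genes removed (0.0722), and without WT replicate 1 (0.0569), WT replicate 3 (0.0553) or both number 1 libraries (0.0606). Ifit1 rose from 66.7 to 172 FPKM and Oas3 fell from 3.23 to 0.412 FPKM. Of 12 antigen presentation genes 7 rose and 1 fell (camera adjusted p = 0.0372; adjusted p = 0.453 with an estimated correlation), with B2m rising from 706 to 969 FPKM and H2-DMb1 falling from 6.49 to 0.910 FPKM. That call also ended with no filter on low values (0.075), short RNA genes removed (0.0624) and without both number 1 libraries (0.0539). Against no change, which is the question fry asks, the interferon and antigen presentation lists had an adjusted p of 0.0929 and 0.141.

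HOX genes, which mark position along the body and limb axes, differed in 28 of 32 tested members, with 23 higher and 5 lower (camera adjusted p = 4.16e-05; adjusted p = 0.0895 with an estimated correlation). The median log2 change was 1.08, or 0.52 without 6 members listed at 0 in each WT library. All 7 tested Hoxc genes were higher. Hoxc8 and Hoxc10 were listed at 0 in each WT library and measured 15.2 to 16.2 and 13.5 to 15.1 FPKM in the libraries labelled Prkcz-/-. Mesenchymal transcription factors had 13 of 22 higher and 5 lower (camera adjusted p = 0.014; adjusted p = 0.187 with an estimated correlation), with En1 rising from 1.79 to 18.7 FPKM and the gut factor Nkx2-3 falling from 20.9 to 1.35 FPKM. SOX factors had 4 of 5 higher and 0 lower (camera adjusted p = 0.0694), and Sox9 rose from 0.306 to 3.49 FPKM. The list of atypical PKC and PAR complex genes had 5 of 13 higher and 3 lower (camera adjusted p = 0.393), with Sqstm1 rising from 179 to 314 FPKM. Unfolded protein and integrated stress genes had 8 of 25 higher and 12 lower (camera adjusted p = 0.698), with Ddit3 rising from 49.1 to 95.2 FPKM and Pdia4 falling from 185 to 127 FPKM.

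**Figure D3:**
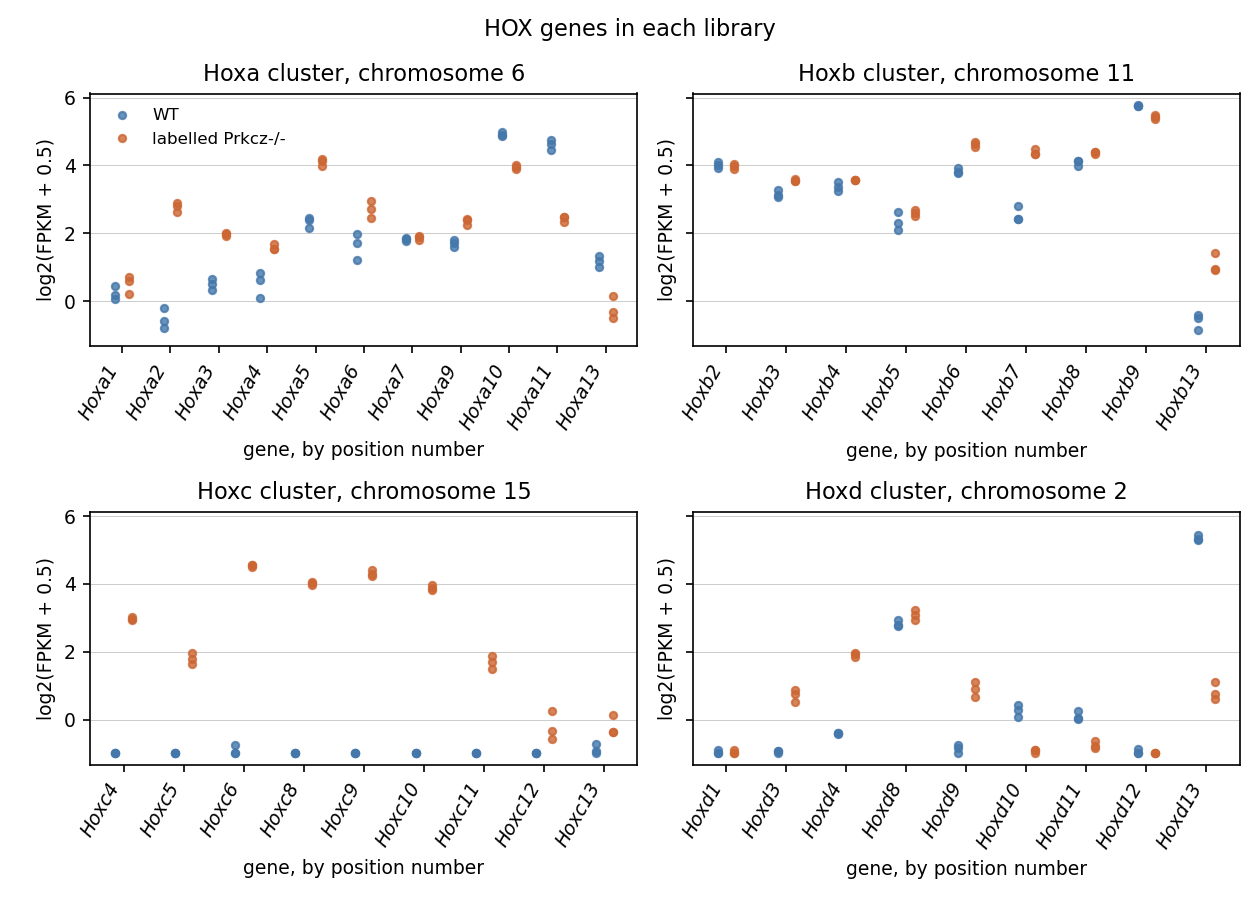
Values of the HOX genes of the 4 clusters as log2(FPKM + 0.5), with 1 point per library and the genes ordered by position number. The Hoxc genes of the WT libraries lie at the floor, where 6 tested members were listed at 0, while Hoxd13 lies at 39.1 to 43.0 FPKM in WT and 1.02 to 1.64 FPKM in the libraries labelled Prkcz-/-.

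Markers of other cell types were mostly near the floor, and most of these lists had too few tested members for a list test. The most abundant epithelial markers, Krt19 and Lgals4, averaged 1.45 and 0.475 FPKM in WT and 0.801 and 0.888 FPKM in the libraries labelled Prkcz-/-. The macrophage markers Cd14 and Cd68 averaged 3.02 and 2.13 FPKM in WT and 3.33 and 1.73 FPKM in the others, and the lymphocyte marker Lck 1.39 and 1.70 FPKM. Of 3 tested endothelial markers 1 rose and 2 fell, with Eng, which fibroblasts also express, falling from 30.5 to 2.74 FPKM and Egfl7 from 7.86 to 5.36 FPKM. All 3 tested mesothelial markers fell, among them Msln from 5.44 to 0.131 FPKM and Cdh3 from 28.3 to 20.3 FPKM. Of 3 tested glial and neuronal markers 2 rose, Tubb3 from 17.6 to 35.4 FPKM and Uchl1 from 6.81 to 20.4 FPKM. Of 3 tested markers of interstitial cells of Cajal 1 rose and 1 fell, and of 2 cartilage and bone markers Col10a1 rose from 0.158 to 8.69 FPKM and Spp1 fell from 82.5 to 64.8 FPKM, a call lost with chromosome medians removed (adjusted p = 0.0542). Pericyte and smooth muscle markers had 4 of 8 higher and 3 lower (camera adjusted p = 0.465). Adipocyte markers had 3 of 5 higher and 0 lower (camera adjusted p = 0.02; adjusted p = 0.187 with an estimated correlation and 0.0732 with quantile normalization), at a low level, with Lpl rising from 0.896 to 5.77 FPKM. Xist, of the inactive X chromosome, measured 48.3 ± 4.32 and 50.4 ± 6.79 FPKM (SD, n = 3).

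The median log2 change also differed by chromosome. It was 0.25 on chromosome 1, 0.24 on chromosome 10, 0.19 on chromosome 11, 0.29 on chromosome 15 and 0.27 on chromosome 19, and lay between -0.22 and -0.16 on 11 others. Removing chromosome medians was an alternative added after seeing the data. With it, 6050 of the 8336 calls stayed past the threshold in the same direction and 59 passed it in the other direction. The remaining calls no longer passed the threshold. Of 1315 calls with a log2 change of at least 1, 1309 were kept.

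**Figure D4:**
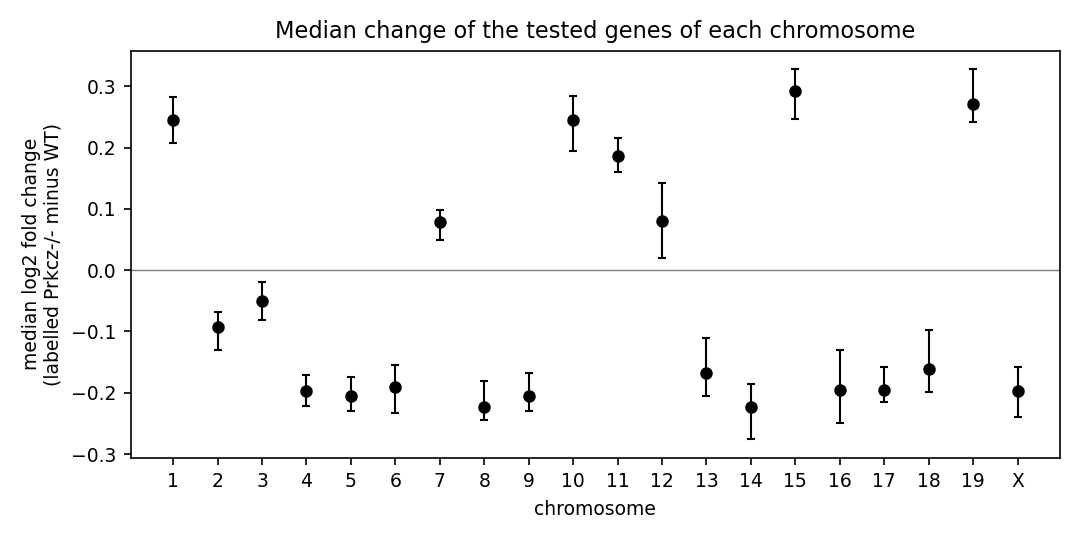
Median log2 fold change of the tested genes on each chromosome, libraries labelled Prkcz-/- minus WT, with 95% bootstrap intervals over genes. Chromosomes 1, 10, 11, 15 and 19 lie between 0.19 and 0.29, and 11 others between -0.22 and -0.16.

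The gene list counts adjusted over the list alone were the same, apart from 18 higher and 8 lower for interferon, 12 and 3 for NF-kB, 4 and 17 for glycolysis, 9 and 13 for stress, 5 and 15 for NRF2, and 13 and 4 for immediate early genes. At the preset correlation 19 lists were higher and 6 lower, and 0 were called with an estimated correlation, where 6 had an unadjusted p under 0.05, while fry, against no change, called 28.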

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

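Tests added after seeing the data were those with chromosome medians removed, without both number 1 libraries, and without short RNA genes. With a log2 change of at least 1 added to the threshold, 884 genes were higher and 431 lower. Over the other settings the numbers of genes higher and lower stayed within 1.5 times of 3825 and 4511. Rescaling without short RNA genes gave 4464 higher and 3710 lower. Leaving out 1 library gave 3477 to 3813 higher, 4152 to 4320 lower, and 23 to 25 gene lists. Log2 changes were then 1.41 to 1.59 for Prkcz, 4.22 to 4.82 for Sox2, 7.51 to 7.67 for Sfrp1 and 0.69 to 0.88 for Sfrp2, all past the threshold. Without both number 1 libraries, which had the highest Mir6236 share in each group (3.35% and 2.36%), 3372 genes were higher and 3968 lower. Camera with an estimated correlation called 0 of the 33 lists. The estimate lay below the preset 0.01 for the cholesterol (-0.036), cytokine (-0.042), fibroblast subset (-0.026) and adipocyte (-0.219) lists. It was also below 0.01 for the p53 and senescence list (-0.004) and, narrowly, for the DNA replication list (0.009). For these lists that argues against a higher correlation between members as what ended the call. Other called lists had higher estimates, up to 0.794 for interferon, and for them the cause was not tested. At the preset correlation, at least 1 other setting ended the call of the cytokine, antigen presentation, interferon, AP-1, NRF2, adipocyte and beta-catenin lists, at an adjusted p of 0.0512 to 0.107. Fry, which tests a list against no change rather than against other genes, did not call antigen presentation (0.141) or interferon (0.0929). Direction turned for 3 lists that were not called: myofibroblast genes under fry (median 0.17), unfolded protein genes under quantile normalization (median 0.0201) and fry (median -0.085), and pericyte markers at a mean of at least 1 FPKM (median -0.14). The cause was not tested. Among single genes, 3 that were not called changed direction: Cd14 (-0.0942) and Lck (-0.0281) under quantile normalization, and Xist without both number 1 libraries (-0.0189) and over single libraries left out (-0.0376 to 0.1567). Over all tested genes, replicate numbers showed no clear pairing, with same-number deviations correlated at 0.06, 0.015 and 0.008. A correlation over all genes cannot exclude an effect shared by same-number libraries in a smaller set of genes. With the replicate number as a block 3718 genes were higher and 4375 lower, and not every library correlated best with its own number. Depth, known only as an estimate, limits genes with few reads, such as Prkcz in WT at about 4.0 to 18.4 reads.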

Other observations

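All tests in this part were chosen after the results were seen, apart from the fit on GC content, exon length and expression. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the labelled groups, called as many as 8336 genes, and the highest of the others called 2. The splits are too few for a share under 0.05. Each of the other splits also mixes libraries of both groups, so the group difference adds to its spread. Few calls there were fixed in advance, and the count decides nothing about the source of the difference.

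Among HOX genes chosen after their values were seen, the Hoxa cluster moved both ways. Hoxa2 and Hoxa5 measured 0.196 ± 0.147 and 4.54 ± 0.549 FPKM in WT and 6.33 ± 0.670 and 16.7 ± 1.33 FPKM in the libraries labelled Prkcz-/- (SD, n = 3). Hoxa11 and Hoxa13 measured 24.1 ± 2.36 and 1.77 ± 0.250 FPKM in WT and 4.90 ± 0.319 and 0.373 ± 0.217 FPKM in the others. Hoxb7 measured 5.35 ± 0.950 and 20.5 ± 1.42 FPKM. By cluster, 6 genes were higher and 3 lower for Hoxa on chromosome 6 (median log2 change -0.19), 6 and 1 for Hoxb on chromosome 11 (0.187), 7 and 0 for Hoxc on chromosome 15 (0.293), and 4 and 1 for Hoxd on chromosome 2 (-0.092). Of 22 mesenchymal transcription factors, 7 changed by at least 2 in log2, where 10000 random lists matched on expression held at most 4 (mean 0.46). The 7, named by size after their values were seen, were Prrx1, Prrx2, Tbx3, Lhx9 and En1, which were higher, and Nkx2-3 and Pitx1, which were lower.

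Genes of whole chromosomes moved together between the labelled groups. The SD of the 20 chromosome medians was 0.196, and 10000 shuffles of chromosome labels reached at most 0.039 (permutation p = 1e-04, the smallest they can give). A spline fit on GC content, exon length and expression left 99% of that SD, which argues against those properties as its source. Across the 20 chromosomes, medians of the genes before and after the middle gene had a Pearson r of 0.978 (permutation p = 1e-05, the smallest 100000 can give) and a Spearman rho of 0.812 (p = 3e-05), and r was 0.971 without the 2 farthest chromosomes, so a difference in chromosome copy number between the cultures may be one source. No DNA was analysed here, and copy number and genotype stay open together, since each group may be 1 culture.

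For the HOX pattern, a shift of the carrying chromosome as the whole source is argued against for Hoxa, where 6 of 9 called genes moved against the chromosome median, for Hoxd, where 5 of 5 calls were kept with chromosome medians removed, and for Hoxc, where 7 of 7 were kept and the shift alone would leave a WT mean of at least 2.22 FPKM for genes listed at 0. For Hoxb, 5 of 7 calls were kept, which argues against the shift as the source of all 7 (by a criterion of most calls kept, set after the counts were seen; the first, all calls kept, and a second on genes chosen by size or direction were set aside), but Hoxb4 (log2 change 0.194, SE 0.072, then 0.007, SE 0.071, adjusted p = 0.936) and Hoxb8 (0.303, SE 0.052, then 0.115, SE 0.054, adjusted p = 0.0977), both named after their values were seen, lost their calls because little change was left, so for them the shift and the genotype cannot be told apart. A second explanation, that the cultures differ in positional identity, for example by the site the cells came from, was tried first with the random-list count above, which decides nothing, since it uses genes that show the pattern. Position number and log2 change over 32 HOX genes then gave a Spearman rho of -0.171 (permutation p = 0.35, 95% bootstrap interval -0.527 to 0.224), but -0.401 over the 25 genes outside the Hoxc cluster, with -0.755 for Hoxa, -0.5 for Hoxd and 0.3 for Hoxb, none of which had a test of its own. The first criterion, rho under 0.2 in size, would have argued against an ordered shift; it was revised after rho was seen because the interval is wide, and the value depends on the Hoxc genes, so origin and genotype cannot be told apart.

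Prkcz was higher in the libraries labelled Prkcz-/-. A rise of its region is argued against, since the 7 tested genes within 0.2 megabases had a median log2 change of -0.455 and a highest of 0.3, and the chromosome 4 median was -0.197. A disrupted gene that is still transcribed (lowest value 1.17 FPKM) and exchanged group labels (log2 change 1.51) cannot be told apart, because gene-level values do not show the deleted part and no other gene has a direction that the labels fix. Reads of the overlapping antisense gene Gm27200 could also have been counted as Prkcz, since the strand setting is not given, and this was not tested. The direction of every comparison rests on whether the group labels hold.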
